A study of Mus musculus with 104 samples.

How the data were processed

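The measured RNA was poly(A)-selected with oligo(dT) beads, fragmented, primed with random and oligo(dT) primers and made strand-specific with dUTP, per the labels. The deposited values are TPM, transcript levels scaled for length and library, which the authors made from reads mapped to mm10 with STAR and counted over exons with HOMER analyzeRepeats, with 1 isoform kept per gene, as the file headers and the submitters' processing notes state. Versions of STAR and HOMER are not given in the sources used here. Each of the 8 tables lists 24940 genes, and 5740 of them are listed with another isoform in at least 1 other table, which is 1 reason why values were tested only within a table. TPM summed to 510684 to 574479 per library. Because HOMER's TPM divide whole reads by length and depth, the reads could be recovered. All 104 libraries gave whole numbers for 100% of their low values (up to 20 reads, within 0.1 of a read). Recovered reads ran from 7830287 to 27777000 per library, and genes with few reads are read less surely in the shallower libraries.

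No column lacked a sample. Of 69 pairs of replicate libraries 0 were identical, with a chi-square per degree of freedom between replicates of 1.56 to 53.42. TPM summed over exons cannot show which exons were read, so a deletion of part of a gene can leave its TPM unchanged. Reads of near-identical copies, such as the hemoglobin genes, Rpl34 and its pseudogene, or Plet1 and Plet1os, cannot be assigned surely.

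Tests were run in limma 3.58.1 under R 4.3.3, one model per table with a mean per group and shared spread, on log2(TPM + 1), with moderated variances that follow the mean. Genes with at least 4 TPM in 2 or more libraries were tested. Calls needed a Benjamini-Hochberg adjusted p below 0.05 and a change of at least 2-fold, in 43 comparisons. Standard errors are the moderated ones. Differences between responses (genotype by treatment, LY411575 against antibody) were tested as interactions in the same models. Group tests used camera with a preset correlation of 0.01, beside a correlation estimated from the residuals, on 24 lists holding 349 genes, which were Kupffer identity, monocyte, Notch targets, TGF-beta SMAD targets, LXR targets, cholesterol synthesis, lipid-associated macrophage, inflammatory response, interferon response, cell cycle, MHC class II, iron and heme handling, complement, dissociation stress, hepatocyte, liver sinusoidal endothelium, periportal endothelium, pericentral endothelium, stellate cell and fibroblast, neutrophil, lymphocyte, dendritic cell, erythroid, and Notch ligands, receptors and niche signals. A further 3 lists of 200 genes were taken from the first table, the called genes with the largest differences between Kupffer cells and monocytes in each direction and those highest at 24 h, and were used in the other tables only. The tables were handled and the figures drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

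Position between monocyte and Kupffer cell was a library's median over called genes of the distance from the monocyte mean, as a percentage of that to the Kupffer mean. Calls shared between tables were counted over genes tested in each table, beside the product of the call rates.

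Named genes followed a rule. It took Nr1h3, Smad4 and Stab2, list members as counts with examples of large called differences, and from each comparison up to 8 called genes per direction with the largest differences, a mean of at least 10 TPM in the higher group and libraries that did not overlap between groups (interactions without that last part). Names of unnamed transcripts and small RNAs were passed over. The time-course genes drawn or given over all times (Clec4f, Cd5l, Timd4, Slc40a1, Ccr2, F13a1, Gpnmb and Mki67), and Rpl34, Rpl30, Hmgn2 and Morf4l1, are list members or were chosen after their values were seen.

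Other settings chosen in advance were a pseudocount of 0.25, no expression filter, quantile normalization, the estimated correlation, a block for the replicate numbers, and leaving out each library. Where that leaves a group with 1 library, its spread is assumed to be that of the other groups. After the data were seen, limma-voom on the recovered reads, fits within Kupffer cells or BMDMs alone and further sets of shared calls were added.

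The method was tested on simulated data with 200 changed genes at a dispersion of 0.04. It recovered 72 to 94% of 3-fold and 99 to 100% of 6-fold changes in 8 comparisons with 9 to 20 false calls, and limma-voom 93 to 99% of 3-fold changes with 4 to 11 false calls.

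Some labels disagree. BMDM libraries titled 72 h carry a 24 h DLL4 label, and the title was followed. Control libraries of the LY411575 and antibody experiments carry the drug or antibody in a label, and the title was followed. Smad4-deleted BMDMs are labelled with Clec4f-cre where the series design names LysM-cre. The macrophages of the LY411575 and antibody experiments are labelled C57BL/6J where the design names toxin receptor mice, and replicate numbers differ between title and description in the antibody experiment. Cultured bone marrow monocytes have column names that read BMDM. The STAB2-low libraries carry a library date of their own, and Kupffer library 31 a library tag of its own.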

Results

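RNA was measured in 104 libraries of mouse blood monocytes, liver macrophages, liver cells sorted on STAB2 and cultured bone marrow cells, in 47 groups of 2 to 4 libraries. The values come as 8 tables, and each table was tested alone. The first table follows the refilling of the liver macrophage niche. Kupffer cells, the resident macrophages of the liver, are removed with diphtheria toxin in mice where Cre recombinase driven by Clec4f turns on a toxin receptor, and incoming monocytes take their place as repopulating liver macrophages. These were collected 12, 24, 48, 72, 168 and 336 h after toxin in 2, 3, 2, 2, 3 and 3 libraries, beside 4 libraries of blood monocytes with high Ly6C and 3 of Kupffer cells from mice given PBS. Recovered reads ran from 9674557 to 20458074 per library in this table.

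The second table holds Kupffer cells and bone marrow-derived macrophages (BMDMs) with or without deletion of Nr1h3, which encodes the sterol-sensing nuclear receptor LXR-alpha (10 libraries in 5 groups, 12504658 to 27777000 reads). The third holds liver cells sorted as low, intermediate or high for STAB2, a scavenger receptor of sinusoidal endothelium (6 in 3 groups, 13920946 to 18944279 reads). The fourth holds Kupffer cells with or without deletion of Smad4, the shared partner of the SMAD proteins that carry TGF-beta and BMP signals (7 in 3 groups, 12855508 to 17211986 reads). The fifth holds control and Smad4-deleted BMDMs given the Notch ligand DLL4, TGF-beta or DAPT, an inhibitor of the gamma-secretase that releases active Notch (20 in 10 groups, 8378141 to 18250416 reads). The sixth holds C57BL/6J BMDMs given DLL4, TGF-beta or the synthetic sterol DMHCA, an LXR ligand (18 in 9 groups, 7830287 to 18633456 reads). The seventh holds liver macrophages 24 h after toxin from mice given the gamma-secretase inhibitor LY411575 or antibodies to the Notch ligands DLL1 and DLL4 (11 in 4 groups, 13891090 to 15751553 reads). The eighth holds bone marrow monocytes cultured with DLL4, TGF-beta or desmosterol, a cholesterol precursor that is a natural LXR ligand (10 in 5 groups, 15009036 to 17605469 reads).

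A gene counts as higher or lower where limma gave a Benjamini-Hochberg adjusted p below 0.05 and a change of at least 2-fold. Log2 differences are given ± the limma standard error (SE) on log2(TPM + 1), where TPM is the transcript level scaled for length and library, a scale that understates changes of genes with low TPM. TPM are given as mean ± SD. The labels do not say whether the libraries of a group came from separate animals or cultures, so the p-values measure the spread between these samples. The groups of genes read beside the single genes were 24 lists fixed before the data were examined. Camera tests were adjusted over the lists with 3 or more measured genes, beside an adjusted p with estimated gene correlation. The number of members called when adjusted over the list alone is given where it differs from that over all genes tested.

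How do Kupffer cells differ from the blood monocytes that can replace them? Between the 3 Kupffer libraries and the 4 monocyte libraries, 2180 of 11373 genes were higher in Kupffer cells and 1816 lower (54.6% higher, 48.7% under quantile normalization). Cd5l, a secreted scavenger protein (chromosome 3, 87357881 to 87371074, + strand, on mm10 as for all positions here), stood at 5860 ± 445 against 0.184 ± 0.191 TPM (log2 12.28 ± 0.21, adjusted p = 2.1e-18). Clec4f, a lectin used as a mark of Kupffer cells (chromosome 6, 83644542 to 83656116, - strand), reached 3341 ± 501 TPM and was listed at 0 in all 4 monocyte libraries. The complement receptor gene Vsig4 was higher by log2 11.30 ± 0.17, the iron exporter gene Slc40a1 by 10.39 ± 0.10 and the ficolin gene Fcna by 10.69 ± 0.20. C1qa, C1qb and C1qc, which together encode C1q, a part of the first component of complement, were higher by log2 11.62 ± 0.15, 10.46 ± 0.26 and 11.32 ± 0.25. Nr1h3 (chromosome 2, 91184061 to 91195035, - strand) stood at 392 ± 51.2 against 3.82 ± 1.38 TPM (log2 6.39 ± 0.19).

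Monocyte genes were lower in Kupffer cells. F13a1, the gene for a clotting factor subunit, fell from 1161 ± 187 to 0.146 ± 0.202 TPM (log2 -9.99 ± 0.28, adjusted p = 1.5e-15), and the chitinase-like gene Chil3 changed by log2 -9.44 ± 0.40. The chemokine receptor gene Ccr2 changed by log2 -8.63 ± 0.28, Ly6c2, which encodes the sorting antigen Ly6C, by -7.81 ± 0.45, and S100a4 by -7.68 ± 0.27. All 17 monocyte list genes were lower (camera adjusted p = 8.8e-09, 0.017 with estimated correlation) and all 21 Kupffer identity genes higher (camera adjusted p = 1e-16, 0.00033 with estimated correlation).

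Several functions moved with identity. Of 17 LXR targets 11 were higher and 1 lower, led by Mertk at log2 8.35 and Apoc1 at 7.39 (camera adjusted p = 1.9e-05, 0.0069 with estimated correlation). Iron and heme handling had 11 of 12 genes higher (camera adjusted p = 1.6e-07, 0.0069 with estimated correlation), and complement 9 higher and 1 lower of 11 (camera adjusted p = 3e-06, 0.019 with estimated correlation). Cholesterol synthesis had 1 of 21 genes higher and 10 lower, 11 lower when adjusted over the list alone (camera adjusted p = 0.019, 0.38 with estimated correlation). Inflammatory response genes were higher in 9 cases and lower in 1, MHC class II in 5 and 1, Notch targets in 3 and 2, and TGF-beta targets in 7 and 2. Interferon genes split 3 higher and 4 lower, lipid-associated macrophage genes 7 and 2, and dendritic cell genes 4 and 3. Of the Notch ligands, receptors and niche signals 4 were higher and 3 lower, 2 neutrophil genes were lower, and 9 of 11 lymphocyte genes were higher, 10 adjusted over the list alone.

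Genes of other liver cells were higher in the Kupffer libraries. All 17 hepatocyte genes were higher (camera adjusted p = 1.2e-05, 0.38 with estimated correlation), as were 16 of 17 sinusoidal endothelium genes with 1 lower (camera adjusted p = 3.7e-07, 0.38 with estimated correlation) and 6 of 7 stellate cell genes. Periportal endothelium had 4 of 5 genes higher and pericentral endothelium 4 higher and 1 lower. The hemoglobin genes ran the other way, with Hba-a1 at 968 ± 780.2 TPM in monocytes, although the near-identical hemoglobin copies share reads, and all 6 erythroid genes were lower (camera adjusted p = 0.017, 0.38 with estimated correlation).

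How fast does an incoming monocyte take on Kupffer cell RNA? Each time point after toxin was compared with the 4 blood monocyte libraries. At 12 h (2 libraries) 1418 genes were higher and 1449 lower, then 2009 and 1793 at 24 h (3 libraries), 2347 and 1908 at 48 h (2), 2431 and 1788 at 72 h (2), 1843 and 1453 at 168 h (3), and 1816 and 1682 at 336 h (3). The balance depends on scaling. Under quantile normalization 46.8, 48.3, 47.7, 49.9 and 48.6% of called genes were higher from 24 h on, against 52.8, 55.2, 57.6, 55.9 and 51.9% here. Of 11 complement genes 8 were higher and 2 lower at 12 h (camera adjusted p = 1e-04, 0.048 with estimated correlation). C1qb stood at 765 ± 204 TPM against 3.74 ± 2.96 in monocytes (log2 7.48 ± 0.29), with C1qa at log2 7.63 ± 0.17 and C1qc at 7.53 ± 0.28. Nr1h3 was already higher by log2 5.73 ± 0.22 and the LXR target Mertk, a receptor for dying cells, by 6.01 ± 0.17. LXR targets had 11 of 17 genes higher at 12 h (camera adjusted p = 2.3e-05, 0.0093 with estimated correlation) and 13 at both 24 and 48 h.

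Lipid-associated macrophage genes were higher early. All 14 were higher at 12 h (camera adjusted p = 5e-09, 0.0093 with estimated correlation), led by Gpnmb at 548 ± 337 TPM (log2 8.14 ± 0.36), Spp1 at log2 7.32 ± 0.59 and the tetraspanin gene Cd63 at 6.43 ± 0.25. The number higher was 13 at 24 h, 12 at 48 and 72 h, and 9 at 168 and 336 h. Gpnmb had dropped to 197 ± 22.3 TPM by 24 h and stood at 3.07 ± 0.714 at 336 h. Dissociation stress genes were lower throughout, 11, 10, 12, 9, 8 and 11 of 14, with Fos at log2 -4.40 ± 0.47 at 12 h. The albumin gene Alb of hepatocytes rose by log2 8.73 ± 0.81 at 12 h, and Clec4g and Igfbp7 of sinusoidal endothelium by 6.74 ± 0.42 and 6.73 ± 0.38. Hepatocyte genes were higher at every time, 16, 16, 15, 17, 17 and 17 of 17. Hba-a1 and Hba-a2 were listed at 0 at 12 h, and Hbb-b1, Hbb-bs and Alas2 were lower by log2 -9.49, -9.48 and -4.57.

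Kupffer identity genes came on in order. Of 21, 12 were higher and 1 lower at 12 h, then 17 at 24 h, 19 at 48 h, 20 at 72 h and all 21 at 168 and 336 h (camera adjusted p with an estimated correlation 0.024, 0.01, 0.0041, 0.0017, 0.00022 and 0.00022 in turn). Slc40a1 was at 614 ± 61.6 TPM at 24 h and 1135 ± 18 at 48 h, against 1988 ± 82.3 in Kupffer cells. Cd5l went from 87.7 ± 38.7 TPM at 24 h to 2223 ± 442 at 48 h and 5986 ± 116 at 168 h. Clec4f came later, from 3.71 ± 0.091 TPM at 24 h through 43.6 ± 2.7 at 48 h to 1872 ± 169.7 at 168 h and 2550 ± 120.1 at 336 h. At 24 h the adhesion gene Vcam1 was higher by log2 7.84 ± 0.25 and Dmpk by 7.25 ± 0.14, and at 336 h the langerin gene Cd207 by 10.29 ± 0.38. All 12 iron and heme genes were higher at 336 h, after 9 at 12 h and 11 at the times between.

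Monocyte list genes were lower in 10 of 17 cases and higher in 1 at 12 h (11 lower adjusted over the list alone), 16 at 24, 48 and 72 h, and all 17 at 168 and 336 h. Serpinb10 and Vcan were lower by log2 -6.05 and -5.84 at 24 h, and the fibronectin gene Fn1 by -6.99 at 48 h. F13a1 reached log2 -10.06 ± 0.28 at 168 h and Chil3 -9.46 ± 0.40 at 336 h. The cell cycle turned on between these steps. Of 18 genes, 2 were higher and 1 lower at 12 h, 13 higher at 24 h, all 18 at 48 h (camera adjusted p = 2.7e-08, 0.29 with estimated correlation) and at 72 h, then 9 and 10 at 168 and 336 h. Mki67 was at 76.4 ± 6.12 TPM at 48 h, 75.1 ± 7.4 at 72 h and 16.7 ± 5.57 at 168 h, against 7.66 ± 1.19 in monocytes. Cholesterol synthesis genes were lower in 3 cases at 12 h and 13, 12, 12, 13 and 12 afterwards. MHC class II genes were higher in 5, 6, 4, 2, 5 and 6 of 9 cases.

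**Figure D1:**
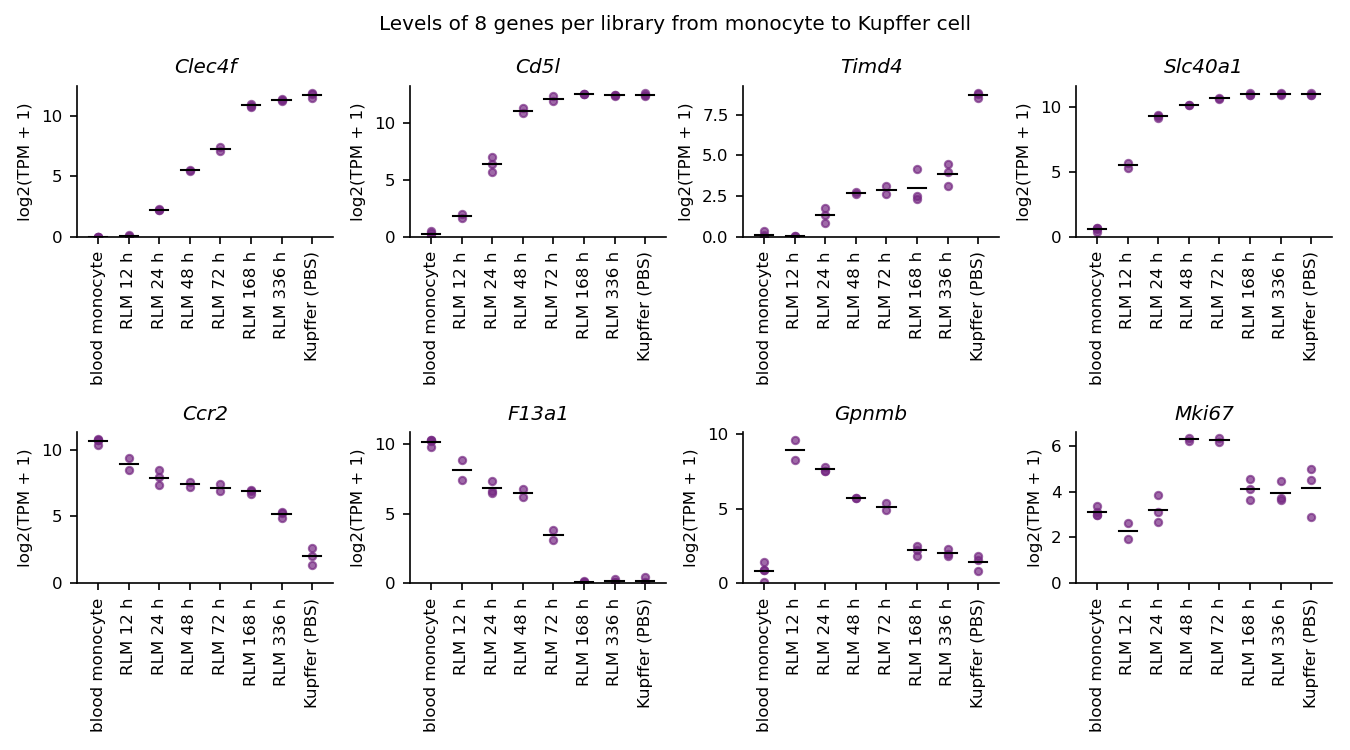
Levels of Clec4f, Cd5l, Timd4, Slc40a1, Ccr2, F13a1, Gpnmb and Mki67 in every library of blood monocytes, liver macrophages 12 to 336 h after toxin, and Kupffer cells.

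The path from monocyte to Kupffer cell was also measured over whole gene sets. For genes higher in Kupffer cells than in monocytes, the 12 h libraries stood 42 ± 6% of the way from the monocyte to the Kupffer mean (mean ± SD over libraries), the 24 h libraries 69 ± 8.3%, and those at 48, 72, 168 and 336 h 72.4 ± 0.2%, 83.7 ± 3.6%, 80.2 ± 5.1% and 80.1 ± 0.1%. Genes lower in Kupffer cells had gone 57.5 ± 15% at 12 h, 79.3 ± 5.3% at 24 h and 92.5 ± 1.1% at 336 h, with 84.4 ± 5.7%, 87 ± 3.5% and 83.9 ± 4.4% at 48, 72 and 168 h. These percentages rest on genes chosen from the same monocyte and Kupffer libraries that mark the ends of the scale.

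**Figure D2:**
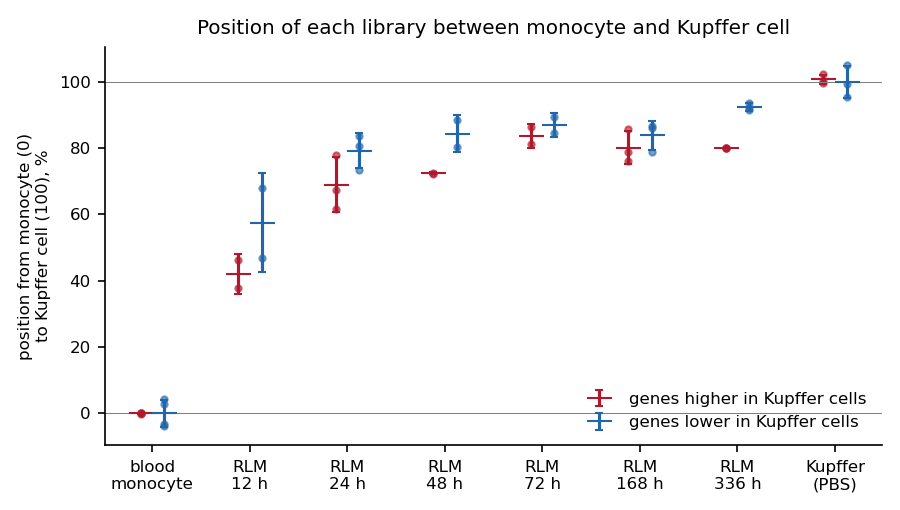
Distance from the blood monocyte mean to the Kupffer cell mean covered by each library after toxin, for genes higher and for genes lower in Kupffer cells.

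What still separates a refilled macrophage from a Kupffer cell? Against the 3 Kupffer libraries, 1150 genes were higher and 1560 lower at 12 h, 780 and 890 at 24 h, 1168 and 931 at 48 h, 755 and 490 at 72 h (699 and 620 under quantile normalization), 145 and 309 at 168 h (205 and 311), and at 336 h 435 in all with 329 lower. Timd4, which encodes a receptor for dying cells (chromosome 11, 46810799 to 46844333, + strand), stood at 14.6 ± 6.8 against 420.3 ± 42.4 TPM at 336 h (log2 -4.86 ± 0.38, adjusted p = 2.2e-07). Lepr, the leptin receptor gene, was lower by log2 -5.40 ± 0.38, the complement gene C2 by -5.24 ± 0.36, Cd209f by -4.65 ± 0.33 and the scavenger receptor gene Colec12 by -4.29 ± 0.52. Timd4, Lepr, C2, Cd209f and Colec12 also led at 168 h, with C6 at -3.44 and Postn at -3.32.

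At 336 h the chemokine receptor genes Cx3cr1 and Ccr2 were still higher, at 40.4 ± 1.95 and 34.6 ± 5.53 TPM against 3.17 ± 0.737 and 3.33 ± 1.89 (log2 3.32 ± 0.26 and 3.12 ± 0.30). The antigen presentation genes H2-Eb1, H2-Aa and H2-Ab1 were higher by log2 2.49 ± 0.47, 2.21 ± 0.46 and 2.08 ± 0.48, among 6 of 9 MHC class II genes (camera adjusted p = 0.00023, 0.75 with estimated correlation). Sinusoidal endothelium genes were lower in 9 of 17 cases (camera adjusted p = 0.00011, 0.75 with estimated correlation). Under quantile normalization 39.6% of the called genes were higher at 336 h, against 24.4% in the main test.

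Kupffer identity genes were lower than in Kupffer cells in 19 of 21 cases at 12 and 24 h, then 17, 12, 6 and 5, with 1 higher at 336 h (camera adjusted p = 0.0018, 0.36 with estimated correlation). Early libraries were marked by Chil3 (log2 9.16 ± 0.48 at 12 h), Emp1 (6.77 ± 0.47) and Cd93 (6.38 ± 0.21), while the scavenger receptor gene Marco stood at 0.561 ± 0.105 against 825 ± 253 TPM and Vsig4 was lower by log2 -11.25. Cx3cr1 was higher by log2 6.83 ± 0.26 at 24 h and 6.74 ± 0.29 at 72 h, and Ccr1 by 6.32 ± 0.39 at 24 h. Cbr2 was higher at 48 h by 6.86 ± 0.25. The potassium channel gene Kcnj16 was lower by log2 -6.07 at 24 h and -5.11 at 72 h, and C6 by -8.69 at 48 h. All 18 cell cycle genes were higher at 48 h (camera adjusted p = 1.1e-08, 0.37 with estimated correlation) and 72 h (camera adjusted p = 1.1e-09, 0.38 with estimated correlation). Hepatocyte genes were lower in 15 of 17 cases at 48 h (camera adjusted p = 0.00034, 0.65 with estimated correlation).

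What depends on Nr1h3 in Kupffer cells? The targeted gene itself stood at 409 and 393 TPM in the control libraries, 391 and 422 in the TIM4-positive and 341 and 395 in the TIM4-negative Kupffer cells labelled Nr1h3 knockout. TPM summed over exons cannot show the loss of some exons, so these are called the libraries labelled Nr1h3 knockout here. Each group had 2 libraries, and TIM4 is the protein of Timd4, on which the label splits the cells. Against the TIM4-positive controls, 302 of 10558 genes were called in the TIM4-positive libraries labelled knockout, 136 of them lower, and 232 higher and 207 lower in the TIM4-negative ones. Under quantile normalization 48 and 45.5% were higher, against 55 and 52.8% here. The chemokine receptor gene Ccr3 stood at 268 ± 6.1 against 9.96 ± 0.689 TPM in TIM4-positive cells (log2 4.62 ± 0.08, adjusted p = 3.4e-08) and was higher by 4.53 ± 0.08 in TIM4-negative cells. Sort1, the sorting receptor gene, rose by log2 4.10 ± 0.10 in TIM4-positive cells, Sh2d1b1 by 3.76 ± 0.13, B4galnt1 by 3.31 ± 0.51, Cx3cr1 by 3.23 ± 0.13 and the collagenase gene Mmp13 by 2.96 ± 0.20.

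Kupffer identity genes fell. Of 21, 7 were lower in TIM4-positive cells (camera adjusted p = 5.3e-10, 0.051 with estimated correlation) and 10 in TIM4-negative cells (camera adjusted p = 8.8e-17, 0.015 with estimated correlation). Cd5l, an LXR target in macrophages, was at 855 ± 54.3 TPM in TIM4-positive and 315 ± 38.4 in TIM4-negative cells against 5788 ± 123 in controls (log2 -2.76 ± 0.12 and -4.20 ± 0.12). The potassium channel gene Kcna2 was lower by log2 -3.01 ± 0.19 and -4.85 ± 0.19 and the cadherin gene Cdh5 by -2.07 ± 0.07 in TIM4-positive cells. LXR targets were lower in 4 of 17 cases, including Scd1 (log2 -2.37), Apoc1 (-1.47) and Pltp (-1.07), in TIM4-positive cells (camera adjusted p = 0.0092, 0.3 with estimated correlation) and in 4 in TIM4-negative cells (camera adjusted p = 0.00038, 0.19 with estimated correlation). Apoc1 lost its call without control library 1 (log2 -1.31), without either TIM4-positive library labelled knockout (-1.33 and -1.60) and in a fit of the Kupffer libraries alone (-1.47, a test chosen after the values were seen), and Pltp under quantile normalization (-0.89). The LXR list lost its call in TIM4-positive cells without control library 2 (median log2 -0.01), and in both fractions under quantile normalization (-0.035 and -0.164). Btbd11, Mefv and the arginase gene Arg2 were lower by log2 -4.34 ± 0.13, -3.82 ± 0.16 and -3.32 ± 0.23 in TIM4-positive cells. Hba-a1 fell from 25.2 ± 1.92 to 2.04 ± 0.875 TPM, with 4 of 5 erythroid genes lower (camera adjusted p = 1.2e-06, 0.077 with estimated correlation), and 2 of 16 cell cycle genes were higher (camera adjusted p = 2e-05, 0.43 with estimated correlation).

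The TIM4-negative libraries labelled knockout differed from the TIM4-positive controls both in label and in TIM4. Timd4 itself stood at 5.84 and 5.22 TPM there, 266 and 315 in TIM4-positive cells labelled knockout and 532 and 556 in controls. Ccr1 was higher by log2 4.89 ± 0.08, Cx3cr1 by 4.39 ± 0.13, Gpr141 by 4.26 ± 0.45, Klra17 by 4.15 ± 0.30 and Sirpb1a by 3.90 ± 0.15. Kcnj16, Ccdc148 and C6 were lower by log2 -4.78 ± 0.17, -4.58 ± 0.17 and -4.22 ± 0.14. Of the 200 genes with the largest rise from monocytes to Kupffer cells in the first table, 29 were lower and 7 higher in TIM4-positive cells (camera adjusted p = 1e-10, 0.008 with estimated correlation), and 40 and 10 in TIM4-negative cells (camera adjusted p = 1.7e-19, 0.0019 with estimated correlation). Of 130 measured genes highest in monocytes, 28 were higher and 9 lower in TIM4-positive cells and 39 higher and 9 lower in TIM4-negative cells (camera adjusted p = 2.9e-05, 0.0028 with estimated correlation).

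Does Nr1h3 matter in cultured macrophages without a liver? In BMDMs after a 7-day culture the targeted gene did fall, from 41.9 and 43.3 TPM in the 2 wild-type libraries to 8.05 and 8.81 in the 2 knockout libraries (log2 -2.21 ± 0.08, adjusted p = 1.7e-05). Only 3 genes were higher and 41 lower. The lipid carrier gene Apoe rose from 1780 ± 11.9 to 4238 ± 61.7 TPM (adjusted p = 0.0055) and Wdfy1 by log2 2.02 ± 0.32. Lrmda fell by log2 -3.07 ± 0.22, U90926 by -2.13 ± 0.15, Dmwd by -2.03 ± 0.16, Cxcl3 by -1.91 ± 0.26 and Ifitm6 by -1.63 ± 0.18. Of 16 cell cycle genes 7 were lower, among them Ube2c and Mki67 at -1.39 and -1.21 (camera adjusted p = 5.3e-14, 0.27 with estimated correlation). The count of 44 depended on single libraries, and was 22 under quantile normalization and 87 in limma-voom.

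Which genes go with STAB2 level in sorted liver cells? Stab2 (chromosome 10, 86841210 to 87007942, - strand) was at 116 and 67 TPM in the low, 1419.5 and 1190.1 in the intermediate and 1713 and 1575 in the high fraction, 2 libraries each. In the low fraction 856 of 10576 genes were higher than in the high fraction and 586 lower (739 and 699 under quantile normalization). The low libraries carry another library date than the other fractions, so date and fraction cannot be separated. The von Willebrand factor gene Vwf, made by endothelium of larger vessels, stood at 1522 ± 122 against 1.76 ± 1.04 TPM (log2 9.16 ± 0.56, adjusted p = 0.00014). The matrix genes Fbln2 and Eln were higher by log2 8.42 ± 0.43 and 7.77 ± 0.54, Fmo2 by 7.73 ± 0.28, Cyp1a1 by 7.46 ± 0.88 (11.81 and not called in limma-voom), and Bmp4 by 7.36 ± 0.33. Niche signals divided, with Tgfb2, Jag1 and Dll1 higher by log2 5.72 ± 0.31, 4.70 ± 0.34 and 2.30 ± 0.17, and Bmp2 lower by -3.03 ± 0.15.

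Sinusoidal endothelium genes were lower in the low fraction, 11 of 17 with 1 higher (camera adjusted p = 6.1e-05, 0.45 with estimated correlation), led by Stab2 at log2 -4.20 ± 0.25 and Lyve1 at -3.93 ± 0.24. Adam23, Wisp1, Flrt1 and Cd209b were lower by log2 -4.32 ± 0.08, -4.24 ± 0.21, -4.16 ± 0.25 and -4.10 ± 0.20. Pericentral genes were higher in 6 of 8 cases, with the Wnt pathway genes Rspo3 and Wnt9b at log2 6.44 and 6.01 (camera adjusted p = 0.00065, 0.45 with estimated correlation). Periportal genes split 3 higher, among them Gja5 at 6.84, and 2 lower. TGF-beta targets were higher in 6 of 16 cases (camera adjusted p = 0.003, 0.4 with estimated correlation) and stress genes in 6 of 14, while hepatocyte genes were lower in 9 of 13, 10 adjusted over the list alone (camera adjusted p = 8.2e-06, 0.45 with estimated correlation) and cell cycle genes in 10 of 15 (camera adjusted p = 1.7e-07, 0.24 with estimated correlation).

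The intermediate fraction had few called genes. Igfbp5, which encodes a growth factor binding protein, was the only called gene, at 21.1 ± 0.519 against 1.54 ± 0.663 TPM (log2 3.15 ± 0.21, adjusted p = 0.024), although 872 genes had an unadjusted p below 0.05 and limma-voom called 11. The fractions share library numbers, and with these as a block 27 genes were called. Without intermediate library 210 the count was 20, and without the high library other than 210 it was 13. Pericentral genes moved up as a group with 0 called and 3 when adjusted over the list alone (camera adjusted p = 3.8e-05, 0.6 with estimated correlation), and cell cycle genes down with 0 called and 2 adjusted over the list alone (camera adjusted p = 8.3e-09, 0.19 with estimated correlation).

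What depends on Smad4 in Kupffer cells? Smad4 (chromosome 18, 73639013 to 73703741, - strand) was at 35.7 and 33.4 TPM in the 2 control libraries, 13.7, 21.5 and 19.5 in the 3 TIM4-positive and 15.1 and 19.6 in the 2 TIM4-negative knockout libraries. In TIM4-positive cells 59 of 9946 genes were higher and 37 lower than in controls, and in TIM4-negative cells 75 and 86. Cx3cr1 stood at 409 ± 158 against 5.43 ± 3.54 TPM in TIM4-positive cells (log2 6.03 ± 0.47, adjusted p = 0.004) and was higher by 6.64 ± 0.52 in TIM4-negative cells. The transporter gene Slco2b1 was higher by log2 5.27 ± 0.40 and 5.14 ± 0.44 in turn, Sort1 by 4.78 ± 0.36 and 3.80 ± 0.40, Cbr2 by 4.31 ± 0.72 and 5.15 ± 0.79, and Rcn3 by 3.48 ± 0.44 and 4.20 ± 0.49. These counts rest on the control libraries. Without control CA 1 gene was called in each comparison, without control AT 14 and 16, without TIM4-positive knockout GC 30, without the TIM4-negative knockout other than TT 29, and without TT 104.

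The TIM4-negative knockouts differ from the controls both in Smad4 and in TIM4, with Timd4 at 4.37 and 4.94 TPM against 619 and 537, so their differences cannot be laid to Smad4 alone. The labels give Clec4f-cre to the knockouts alone, so cre goes with deletion throughout. Clec4f was lower than in controls, by log2 -1.95 ± 0.15 in TIM4-positive and -2.93 ± 0.17 in TIM4-negative cells. Kupffer identity genes were lower in 2 of 21 cases in TIM4-positive cells, the other being Fabp7 at -2.17 ± 0.31, and 1 higher and 4 lower when adjusted over the list alone (camera adjusted p = 3.6e-06, 0.33 with estimated correlation). In TIM4-negative cells 6 were lower, 15 when adjusted over the list alone (camera adjusted p = 6.1e-16, 0.29 with estimated correlation), among them Timd4 itself, the hemoglobin scavenger gene Cd163 at -2.66 ± 0.31 and the BMP target Id1 at -2.26 ± 0.42. Btbd11, Mefv, Ldlrad3, Tgfb3, Arg2 and Il1rn were lower in TIM4-positive cells by log2 -3.05, -2.81, -2.45, -2.33, -2.23 and -2.19. In TIM4-negative cells Lepr, Cxcl13, Tcim, Colec12 and C2 were lower by log2 -5.08, -4.47, -3.64, -3.59 and -3.54, and Ccr2 was higher by 2.83 ± 0.40. Hba-a1 was lower in both, at 0.988 ± 0.859 and 0.609 ± 0.0955 TPM against 23.8 ± 5.67, and of 14 dissociation stress genes 0 were called but 6 were lower in TIM4-positive cells (camera adjusted p = 9.6e-07, 0.39 with estimated correlation) and 11 in TIM4-negative cells (camera adjusted p = 5.8e-08, 0.38 with estimated correlation) when adjusted over the list alone, with median log2 differences of -1.315 and -1.639.

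The Kupffer libraries labelled Nr1h3 knockout and the Smad4 knockouts shared called genes, a test chosen after the values were seen. In TIM4-positive cells 27 genes were higher in both, Cx3cr1 and Sort1 among them, and 15 lower, Clec4f among them. In TIM4-negative cells 36 were higher and 50 lower in both, Timd4 among the latter. In both tables the knockouts carry Clec4f-cre and the controls do not, and the TIM4-negative cells are set against controls with high Timd4. Genes that go with cre or TIM4 are thus shared by design, and no expected number applies. In the TIM4-positive pair the higher and lower counts were 5 and 1 without Smad4 control AT, 0 and 0 without control CA, and 9 and 6 without knockout GC. In the TIM4-negative pair they were 4 and 5 without AT and 0 and 1 without CA.

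What do DLL4 and TGF-beta do to control BMDMs in culture? Each condition had 2 libraries of cells cultured 4 days and treated for 24 h. DLL4 raised 297 of 10267 genes and lowered 120. Hes1, the classic Notch target (chromosome 16, 30065357 to 30067796, + strand), stood at 21.6 ± 0.672 against 0.239 ± 0.15 TPM (log2 4.19 ± 0.18, adjusted p = 4.8e-10). The Notch target list as a group had 1 of 6 genes higher and 1 lower (camera adjusted p = 0.33, 0.49 with estimated correlation). The transporter gene Abcg3 rose by log2 4.43 ± 0.11, Apol7c by 4.20 ± 0.25, the nuclease gene Dnase1l3 by 4.12 ± 0.10, Adgre4 by 3.78 ± 0.14, and Pxdc1, Clec4n and Ms4a4a by 3.71, 3.46 and 3.43. Kupffer identity genes rose in 9 of 17 cases (camera adjusted p = 0.00035, 0.072 with estimated correlation), with the heme-responsive factor gene Spic at log2 3.29 ± 0.24, Nr1h3 at 2.56 ± 0.15, Clec4f at 2.50 ± 0.18 and Slc40a1 at 2.42 ± 0.10. All 9 MHC class II genes rose, with their regulator Ciita at 3.17 (camera adjusted p = 1.2e-12, 0.039 with estimated correlation), and 5 of 15 LXR targets (camera adjusted p = 0.0023, 0.24 with estimated correlation). The chemokine genes Ccl2 and Ccl7 fell by log2 -4.83 ± 0.53 and -4.68 ± 0.40, Nanos1 and Pcdh7 by -2.42 and -2.40, the cyclin gene Ccnd1 by -1.96 and Spp1 by -1.95.

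With DAPT added to DLL4, 35 genes were higher and 180 lower than under DLL4 alone. Hes1, Dnase1l3, Apol7c, Ocstamp and Asb2 fell by log2 -3.95 ± 0.18, -4.13 ± 0.10, -3.89 ± 0.25, -3.38 ± 0.22 and -3.24 ± 0.16, while Ccl2, Nanos1, Mt2 and Ccnd1 rose by 2.92 ± 0.53, 1.92 ± 0.22, 1.55 ± 0.26 and 1.47 ± 0.40. Ccnd1 was not called without DLL4 library 2 (1.35) or either library with DAPT (1.44 and 1.51). Kupffer identity genes fell in 8 cases (camera adjusted p = 1.9e-06, 0.035 with estimated correlation) and all 9 MHC class II genes fell (camera adjusted p = 4e-17, 0.024 with estimated correlation). Because the DLL4 libraries serve both comparisons, opposite signs are partly built in.

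TGF-beta alone raised 268 genes and lowered 160. Pmepa1, a feedback inhibitor of TGF-beta signaling (chromosome 2, 173224465 to 173276533, - strand), stood at 67.9 ± 10.7 against 0.775 ± 0.254 TPM (log2 5.28 ± 0.14), and Tmem119, known from microglia, rose by 4.90 ± 0.13. F11r, Tmeff1 and Olr1 rose by log2 3.66 ± 0.08, 3.27 ± 0.17 and 3.10 ± 0.19. TGF-beta targets rose in 9 of 19 cases, among them Ldlrad4, P2ry12 and Olfml3 at 2.89, 2.25 and 2.14 (camera adjusted p = 1.1e-10, 4e-04 with estimated correlation), and 5 Kupffer identity genes fell. Ccl7, Ccl2, Mmp13, Clec10a and Mmp12 fell by log2 -3.53, -3.25, -2.99, -2.72 and -2.59. TGF-beta on top of DLL4 raised 269 genes and lowered 415 (39.3% higher, 49.1% under quantile normalization). Pmepa1 rose again by 5.32 ± 0.14, Fam189a2 by 4.25 ± 0.21, Tlr12 by 3.37 ± 0.16, and Dnase1l3 climbed further, to 183 ± 25.8 against 19.6 ± 0.666 TPM. Ccl9, Clec4a1 and Clec4b1 fell by log2 -3.33 ± 0.10, -2.99 ± 0.12 and -2.91 ± 0.18. TGF-beta targets rose in 10 of 19 cases (camera adjusted p = 7e-09, 0.0011 with estimated correlation) and all 18 cell cycle genes fell (camera adjusted p = 5.5e-11, 0.074 with estimated correlation).

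What is left of these responses without Smad4? Smad4 stood at 24.9 and 25.3 TPM in the 2 untreated control libraries and 10.5 and 9.9 in the 2 untreated knockout libraries, and at 20.4 to 26.5 and 8.52 to 11.3 over all 10 libraries of each genotype. Knockout cells answered TGF-beta with 52 genes higher and 4 lower (90 in all in limma-voom), among them Pmepa1 by log2 3.26 ± 0.14, F11r by 2.42 ± 0.08, Tmem119 by 2.23 ± 0.13, Spint1 by 1.95 ± 0.14, Fcrls by 1.77 ± 0.09 and Mtus1 by 1.71 ± 0.12. Clec4b1 and Ppbp fell by log2 -1.19 and -1.15 (Ppbp -0.88 and not called without knockout TGF-beta library 2), and 3 of 19 TGF-beta targets rose, 4 when adjusted over the list alone (camera adjusted p = 3e-13, 0.00015 with estimated correlation). The difference between genotypes was tested directly and called 54 genes higher and 69 lower, 225 in all without control TGF-beta library 1. Tmem119, Pmepa1, Ldhb and Mmp14 answered less in knockout cells, by log2 -2.67 ± 0.19, -2.02 ± 0.19, -1.91 ± 0.40 and -1.69 ± 0.17. Ednrb, Mmp13, Mmp12 and Egr2 fell less, by 2.19 ± 0.18, 2.18 ± 0.17, 2.02 ± 0.11 and 1.90 ± 0.22, and 4 of 19 TGF-beta targets answered less (camera adjusted p = 1.1e-11, 0.00027 with estimated correlation).

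Smad4 knockout cells still answered DLL4. It raised 227 genes and lowered 121, with 1 of 6 Notch targets higher and 1 lower (camera adjusted p = 0.3, 0.5 with estimated correlation), and Dnase1l3 at log2 4.35 ± 0.10, Apol7c at 4.15 ± 0.25, Abcg3 at 3.97 ± 0.11, Spic at 3.47 ± 0.24, Hes1 at 3.28 ± 0.18 and Ccl2 at -3.63 ± 0.53. All 9 MHC class II genes rose (camera adjusted p = 2.4e-13, 0.055 with estimated correlation), and 8 Kupffer identity genes rose and 2 fell (camera adjusted p = 0.0011, 0.071 with estimated correlation). The direct test of genotype on the DLL4 answer called 0 genes, with 843 at an unadjusted p below 0.05, 1 called in limma-voom, 3 with no expression filter and 2 without knockout DLL4 library 2. Untreated knockout cells differed from controls in 77 genes higher and 39 lower, led by the prostaglandin dehydrogenase gene Hpgd at log2 3.53 ± 0.15, then Il11ra1, Ms4a4a, Tns1, Dcstamp and Pltp at 1.97, 1.92, 1.77, 1.71 and 1.71. Ms4a4a was not called without untreated control library 2 (1.64). Id1 was lower by log2 -1.83 ± 0.36, Ccl7 by -2.73 ± 0.40 and Ccr3 by -1.88 ± 0.12. The largest falls, Rpl34, which lies over its pseudogene, at -6.14 ± 0.13, Rpl30 at -4.91 ± 0.34 and Hmgn2 at -3.01 ± 0.19, are weighed in the closing section.

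**Figure D3:**
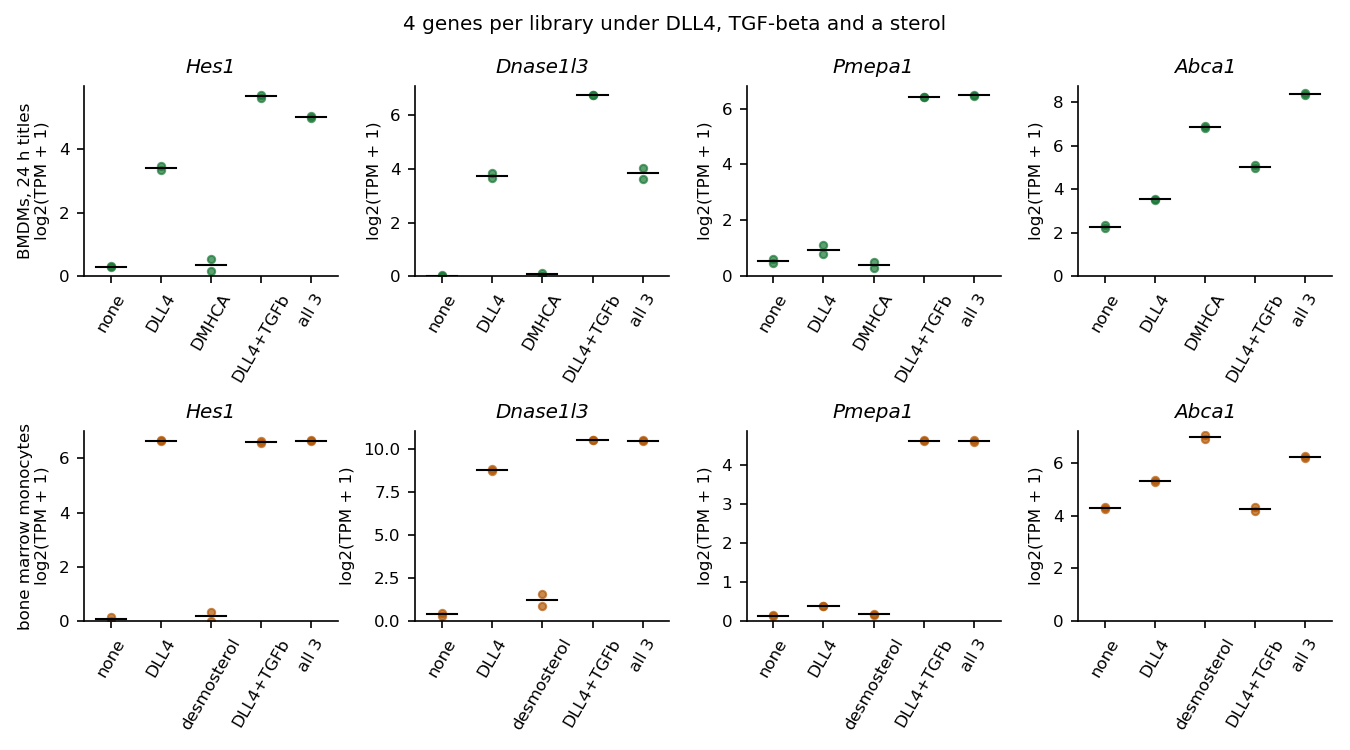
Levels of Hes1, Dnase1l3, Pmepa1 and Abca1 in libraries of sixth-table BMDMs and bone marrow monocytes, by treatment.

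**Figure D4:**
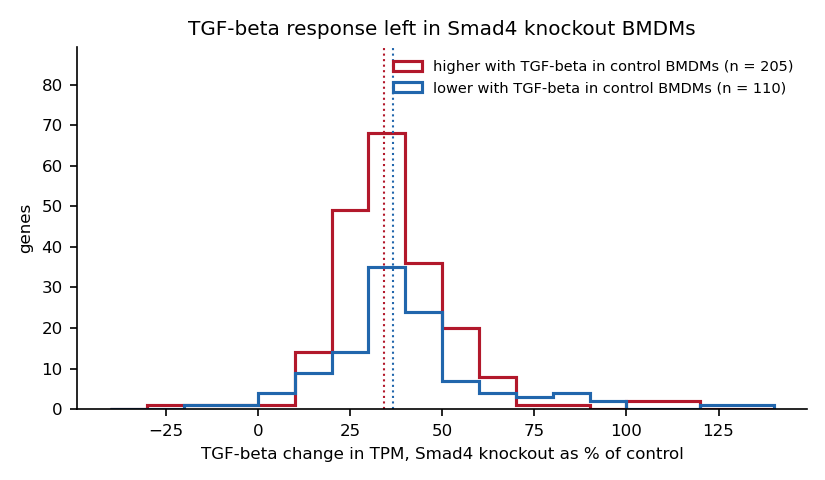
Share of the TPM change with TGF-beta in control BMDMs that was left in Smad4 knockout BMDMs, for 205 genes that rose and 110 that fell in control cells, with dotted medians.

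How do DLL4, TGF-beta and an LXR ligand combine in C57BL/6J BMDMs? All groups had 2 libraries, with treatments titled 24 h or 72 h. At 24 h DLL4 raised 242 of 10908 genes and lowered 58. Abcg3, Apol7c, Ms4a4a and the integrin gene Itga9 rose by log2 4.75 ± 0.33, 4.53 ± 0.56, 4.37 ± 0.16 and 4.20 ± 0.08, and Ocstamp, Dnase1l3, Asb2 and Acp5 by 3.91, 3.74, 3.54 and 3.33. C1qa, C1qc and C1qb rose by log2 2.61 ± 0.13, 1.97 ± 0.07 and 1.88 ± 0.07. Ccl2 fell by log2 -3.12 ± 0.25, and Ccl7, Klf4, Fosl1 and Npy by -2.99, -2.30, -1.92 and -1.67. Kupffer identity genes rose in 6 of 15 cases (camera adjusted p = 0.0012, 0.17 with estimated correlation), MHC class II in 8 of 9 (camera adjusted p = 0.00011, 0.33 with estimated correlation), LXR targets in 6 of 17 (camera adjusted p = 0.0015, 0.17 with estimated correlation) and Notch targets in 1 of 7 at 24 h (camera adjusted p = 0.97, 0.97 with estimated correlation) and 1 at 72 h (camera adjusted p = 0.61, 0.9 with estimated correlation). At 72 h 143 genes were higher and 46 lower (145 and 72 under quantile normalization), with Apol7c at 6.16 ± 0.56, Spint1 at 3.64 ± 0.09, Cd244 at 3.35 ± 0.15, Fcrls at -3.01 ± 0.10 and F13a1 at -2.77 ± 0.14, 7 of 9 MHC class II genes higher (camera adjusted p = 2e-07, 0.15 with estimated correlation) and 5 Kupffer identity genes higher and 1 lower (camera adjusted p = 0.018, 0.22 with estimated correlation).

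DMHCA alone raised 285 genes and lowered 307 at 24 h. The cholesterol pumps Abca1 (chromosome 4, 53030789 to 53159895, - strand) and Abcg1 rose from 3.85 ± 0.262 to 116 ± 5.53 and from 11.1 ± 0.0184 to 228 ± 8.46 TPM (log2 4.59 ± 0.11 and 4.24 ± 0.05). The desaturase genes Scd1 and Scd2 rose by log2 4.66 ± 0.13 and 4.33 ± 0.06, Slc6a12 by 5.10 ± 0.21 and the chemokine gene Cxcl10 by 4.32 ± 0.24. LXR targets rose in 10 cases and fell in 2 (camera adjusted p = 0.00025, 0.055 with estimated correlation). The cholesterol synthesis list hardly moved (mean 26 and 25 TPM, 26.4 and 26 untreated). Mmp8, Ngp and F13a1 fell by log2 -4.03 ± 0.06, -3.92 ± 0.08 and -4.03 ± 0.14. Neutrophil genes were lower in 10 of 11 cases (camera adjusted p = 3.5e-13, 0.0035 with estimated correlation) and monocyte genes in 10 of 16 (camera adjusted p = 1.6e-09, 0.0075 with estimated correlation), while interferon genes rose in 9 of 11 (camera adjusted p = 6e-06, 0.13 with estimated correlation) and inflammatory genes in 8 of 15 (camera adjusted p = 1.5e-06, 0.0075 with estimated correlation).

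TGF-beta on DLL4 raised 252 genes and lowered 162 at 24 h, with Pmepa1 at log2 5.48 ± 0.11, Spsb1 at 4.00 ± 0.10, Tmem119 at 3.82 ± 0.16, Pxdc1 at 3.75 ± 0.16, Slc36a2 at 3.15, Ccl2 at -4.05 ± 0.25 and Ccl9 at -3.60 ± 0.07. TGF-beta targets rose in 7 of 20 cases (camera adjusted p = 1.9e-11, 0.0053 with estimated correlation), and 1 Kupffer identity gene rose and 6 fell. At 72 h 439 genes were higher and 177 lower. Adamdec1, Fam189a2, Ptgs2 and the integrin gene Itgae rose by log2 3.93 ± 0.20, 3.86 ± 0.19, 3.79 ± 0.11 and 3.36 ± 0.19, and Slamf8, Ccl9 and F7 fell by -3.58 ± 0.16, -3.51 ± 0.07 and -3.45 ± 0.19. Kupffer identity genes split 4 higher, with Vsig4 at 2.71, and 3 lower, and TGF-beta targets rose in 10 of 20 cases (camera adjusted p = 5.5e-05, 0.085 with estimated correlation).

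DMHCA on DLL4 and TGF-beta raised 48 genes and lowered 86 at 24 h, and 70 and 498 at 72 h. The neutrophil list did not fall at 24 h (mean 365 and 346 TPM, 345 and 321 without DMHCA). LXR targets rose in 11 of 17 cases at 24 h (camera adjusted p = 3.1e-22, 0.0013 with estimated correlation) and 10 at 72 h (camera adjusted p = 3.5e-15, 0.0054 with estimated correlation), with Scd1 at log2 3.96 ± 0.13 and 3.06 ± 0.13, Abca1 at 3.36 ± 0.11 and 2.63 ± 0.11, and Pltp at 2.37 ± 0.07 and 2.58 ± 0.07. Srebf1, Rnf145 and Dmpk rose by 1.98, 1.96 and 1.76 at 24 h. Of 23 cholesterol synthesis genes 8 fell at 24 h (camera adjusted p = 2.4e-26, 0.0017 with estimated correlation). Dnase1l3, Ocstamp, Hpse and Esam fell by -2.92, -2.50, -2.29 and -2.18.

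At 72 h the falls were broad. Vcam1, Itgae, Ifitm1, Cd4, Vsig4 and Plac8 changed by log2 -3.92 ± 0.38, -3.81 ± 0.19, -3.53 ± 0.18, -3.53 ± 0.30, -3.42 ± 0.29 and -3.35 ± 0.17. All 6 dendritic cell genes were lower (camera adjusted p = 4.1e-07, 0.0073 with estimated correlation), with 10 of 11 neutrophil (camera adjusted p = 5.7e-10, 0.0058 with estimated correlation), 10 of 16 monocyte (camera adjusted p = 4.1e-07, 0.013 with estimated correlation) and 11 of 18 cell cycle genes (camera adjusted p = 1.1e-10, 0.059 with estimated correlation). MHC class II genes were lower in 8 of 9 cases (camera adjusted p = 3e-05, 0.19 with estimated correlation), interferon genes in 7 of 11 (camera adjusted p = 7.1e-05, 0.19 with estimated correlation) and cholesterol synthesis in 8 of 23 (camera adjusted p = 1.5e-09, 0.025 with estimated correlation). Under quantile normalization 26% of the called genes were higher, against 12.3% in the main test.

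Does blocking Notch in the animal change macrophages 24 h after toxin? LY411575 raised 369 of 9885 genes and lowered 262 (3 treated and 2 control libraries). The iron exporter gene Slc40a1 fell from 446 ± 4.1 to 21.6 ± 1.62 TPM (log2 -4.31 ± 0.20, adjusted p = 1.1e-07). Tspan13, the prostaglandin synthase gene Ptgs1, Itga9, the integrin gene Itgax and Spon1 fell by log2 -4.74 ± 0.28, -4.34 ± 0.12, -4.09 ± 0.15, -4.00 ± 0.28 and -3.98 ± 0.20, and Actn1 and Vcam1 by -3.91 and -3.78. Kupffer identity genes fell in 7 of 14 cases, with Cd5l at log2 -3.46 ± 0.21 and Spic at -3.40 ± 0.23, and rose in 1, Fabp7 at 3.06 ± 0.20 (camera adjusted p = 1.8e-05, 0.037 with estimated correlation). MHC class II genes fell in 8 of 9 cases (camera adjusted p = 2e-08, 0.17 with estimated correlation), LXR targets in 4 of 17 (camera adjusted p = 0.00017, 0.067 with estimated correlation) and iron genes in 4 of 12 (camera adjusted p = 0.011, 0.12 with estimated correlation).

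Il7r, Pmp22, Thbs1 and Emp1 rose under LY411575 by log2 4.35 ± 0.29, 4.01 ± 0.19, 3.80 ± 0.35 and 3.79 ± 0.14, and Lonrf3, Spp1, Asns and Clec4d by 3.63, 3.34, 3.25 and 3.13. Monocyte genes rose in 10 of 17 cases and fell in 2, and lipid-associated macrophage genes in 6 and 2 (camera adjusted p = 0.00032, 0.22 with estimated correlation). Of 174 genes highest in monocytes in the time course, 59 rose and 6 fell (camera adjusted p = 1.4e-14, 0.16 with estimated correlation).

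The antibodies to DLL1 and DLL4 raised 67 genes and lowered 138 (4 treated and 2 control libraries). Tspan13, Slc12a2 and Itgax fell by log2 -2.65 ± 0.27, -2.56 ± 0.24 and -2.47 ± 0.27. Emp1 stood at 115 ± 20.6 against 18.2 ± 0.635 TPM (log2 2.58 ± 0.13), Pmp22 rose by 2.35 ± 0.18, Adam8 by 1.85 ± 0.12, Itga6 by 1.75 ± 0.15, and Syngr1 and Pf4 by 1.68 and 1.60. Of the Kupffer identity genes Folr2 and Fabp7 rose by 2.00 ± 0.18 and 1.61 ± 0.19 and Spic fell by log2 -1.64 ± 0.21. MHC class II had 0 genes called with a median log2 of -0.706 (camera adjusted p = 3.1e-06, 0.33 with estimated correlation), and lipid-associated macrophage genes 3 higher and 1 lower (camera adjusted p = 1.4e-06, 0.29 with estimated correlation). Hepatocyte transcripts were lower alongside, with Apoa4, Mat1a and Cyp3a11 at log2 -2.43, -2.20 and -2.10, and 7 of 17 hepatocyte genes lower, 15 adjusted over the list alone (camera adjusted p = 1.4e-06, 0.46 with estimated correlation). Without control library 1 these 3 genes were not called (log2 -1.81, -1.47 and -1.48), nor with no expression filter. Apoa4 was also not called without control library 2 (-3.04) or treated library 1 (-2.43) or 2 (-2.51), and Mat1a without treated library 3 (-2.00). The count of 205 was 133 without control library 1, 132 without treated library 3, 344 without treated library 4, and 367 in limma-voom.

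Both treatments lowered 40 of the same genes where 3.66 would be shared if the calls were independent, Tspan13, Itgax, Spon1 and Ptgs1 among them, and raised 35 against 2.5, Emp1 and Pmp22 among them. They share no libraries. The treatments were also compared directly, as the difference between the changes, with 351 genes higher for LY411575 and 181 lower. Cd5l answered lower by log2 -4.14 ± 0.29, Mrc1 by -3.50 ± 0.12, Cbr2 by -3.40 ± 0.13 and Slc40a1 by -3.33 ± 0.28. Kupffer identity had 8 genes lower and 1 higher (camera adjusted p = 2.6e-07, 0.016 with estimated correlation), LXR targets 5 lower, and 2 higher when adjusted over the list alone (camera adjusted p = 3.3e-07, 0.018 with estimated correlation) and MHC class II 6 lower (camera adjusted p = 2.6e-07, 0.25 with estimated correlation). Il7r and Thbs1 answered higher by 3.86 ± 0.40 and 3.77 ± 0.48, and so did the hepatocyte genes Cyp3a11, Cyp2e1, Cps1 and Tat by 4.52, 4.47, 3.55 and 3.46, with 11 of 17 hepatocyte genes higher, 16 adjusted over the list alone (camera adjusted p = 2.6e-07, 0.43 with estimated correlation). Cyp2e1 was not called when any 1 of the 5 libraries of the LY411575 experiment was left out (4.44 to 4.49) or without antibody control 1 (3.36), nor Cyp3a11 in limma-voom (5.10). The count of 532 was 345 without LY411575 control 1, 323 without LY411575 control 2 and 325 without antibody control 1. The LY411575 libraries are labelled female and the antibody libraries male, so treatment and sex cannot be separated here.

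What do the same signals do to monocytes taken straight from bone marrow? After 48 h of a 2-day culture with DLL4 931 of 10234 genes were higher and 1063 lower, 2 libraries per group. Apol7c stood at 1971 ± 17.7 against 0.888 ± 0.00495 TPM (log2 10.03 ± 0.25, adjusted p = 5.8e-10). Dnase1l3, Asb2, Gbp2b and Tlr12 rose by log2 8.38 ± 0.17, 8.11 ± 0.08, 7.98 ± 0.06 and 6.93 ± 0.07, Ocstamp by 6.80 ± 0.06, Hes1 by 6.57 ± 0.11 and Itgax by 6.53 ± 0.15. All 9 MHC class II genes rose, with H2-Ab1 at 6.23 (camera adjusted p = 2e-07, 0.18 with estimated correlation), with 11 of 13 interferon (camera adjusted p = 2.6e-05, 0.38 with estimated correlation) and 4 of 6 dendritic cell genes. Notch targets split 2 higher and 2 lower of 6 (camera adjusted p = 0.54, 0.61 with estimated correlation). Npy fell from 47.6 ± 3.3 TPM to be listed at 0. Spp1, Ccl2, S100a4 and Pmp22 fell by log2 -5.97 ± 0.10, -5.91 ± 0.12, -5.83 ± 0.18 and -5.56 ± 0.09, and Col18a1, Folr2 and Ccl7 by -5.32, -5.17 and -4.89. Lipid-associated macrophage genes fell in 11 of 14 cases and rose in 2 (camera adjusted p = 0.00031, 0.19 with estimated correlation), and cholesterol synthesis fell in 11 and rose in 1 (camera adjusted p = 1.6e-05, 0.19 with estimated correlation). Kupffer identity genes split 5 higher and 3 lower of 10.

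TGF-beta on DLL4 raised 244 genes and lowered 658 in these monocytes, 41.5% higher under quantile normalization against 27.1% in the main test. Fam189a2, Epcam, Pmepa1 and Spsb1 rose by log2 6.15 ± 0.11, 4.58 ± 0.11, 4.24 ± 0.10 and 3.79 ± 0.09, and Kazn and Ephx2 by 3.82 and 3.75. Plet1 and the overlapping Plet1os, which share reads, rose by 4.64 and 3.99. Dmpk, Mmp8, Pf4, Spic, Mrc1 and the BMP target Id3 fell by log2 -5.27 ± 0.08, -4.89 ± 0.09, -4.80 ± 0.10, -4.65 ± 0.24, -4.39 ± 0.08 and -4.24 ± 0.08. TGF-beta targets split 6 higher and 3 lower of 18, Id1 at -3.13 among the latter. Cell cycle genes fell in 17 of 18 cases (camera adjusted p = 2.2e-11, 0.098 with estimated correlation), interferon genes in 11 of 13 (camera adjusted p = 0.00022, 0.29 with estimated correlation) and Kupffer identity genes in 5 of 10 (camera adjusted p = 0.00042, 0.15 with estimated correlation).

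Desmosterol had a narrow effect, 13 genes higher and 12 lower alone and 13 and 8 on top of DLL4 and TGF-beta. Scd1 rose by log2 2.78 ± 0.11 alone and 2.51 ± 0.11 in the mix, Abca1 by 2.69 ± 0.07 and 1.96 ± 0.07, Abcg1 by 1.90 ± 0.05 and 1.13 ± 0.05, and Scd2 by 1.78 ± 0.05 and 1.28 ± 0.05. Dmpk and Rnf145 rose alone by 1.15 and 1.04, and Cd38, Pltp, Lrp1 and Cd5l in the mix by 1.87, 1.43, 1.13 and 1.04. LXR targets rose in 4 of 16 cases alone (camera adjusted p = 1.5e-17, 0.032 with estimated correlation) and in 6 in the mix (camera adjusted p = 5.8e-25, 0.014 with estimated correlation). Cholesterol synthesis had 0 genes called alone but a median log2 of -0.383 (camera adjusted p = 3.7e-12, 0.063 with estimated correlation), and 1 lower in the mix (camera adjusted p = 8.2e-18, 0.032 with estimated correlation). Thbs1 and Atp6v0d2 fell alone by log2 -1.30 and -1.03, and Egr1, Plet1 and Fos in the mix by -1.38, -1.31 and -1.10. The 25 genes called for desmosterol alone were 16 without untreated library 1, where Rnf145 (0.99) and Atp6v0d2 (-0.95) lost their calls, Atp6v0d2 also without desmosterol library 2 (-0.93). In the mix Cd5l was not called without DLL4 and TGF-beta library 1 (0.92), Fos without library 2 of that group (-0.99) or under quantile normalization (-0.99), and Cd38 without library 2 of that group (1.73) or of the mix (1.84). The 21 in the mix were 37 without DLL4 and TGF-beta library 1 and 41 in limma-voom, and quantile normalization called 15, 11 of them higher.

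Which answers recur across cultures? The tables were tested apart, and calls shared between tables are set beside the number expected if independent. DLL4 was compared at 24 h in the BMDMs of the fifth and sixth tables and at 48 h in bone marrow monocytes. Of the 223 genes tested in all 3 tables that it raised in C57BL/6J BMDMs, 68.6% were raised in all 3 cultures, where 0.495 genes would be, among them Apol7c, Dnase1l3, Asb2, Hes1, Ocstamp and Abcg3. It lowered 24 in all 3 against 0.0393, among them Ccl2, Ccl7 and Spp1. TGF-beta on DLL4 raised 65 in all 3 against 0.0887, such as Pmepa1, Fam189a2, Spsb1 and F11r, and lowered 70 against 0.372 (108 in limma-voom), such as Ccl9, Mrc1 and Clec4a1. DMHCA in BMDMs and desmosterol in monocytes, which differ in cells, time and compound, shared 8 raised genes against 0.259, Scd1, Abca1, Abcg1, Scd2, Rnf145 and Syn1 among them, and 1 lowered, Thbs1, against 0.279. On top of DLL4 and TGF-beta the sterols shared 8 raised genes against 0.0529 and 3 lowered, Plet1 and Plet1os among them, against 0.0463 (1 under a pseudocount of 0.25, 1 or 2 with single libraries left out). The lowered Thbs1 count was 2 at most with single libraries left out.

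How much of the Kupffer difference do DLL4, DAPT or LY411575 move? The first table's 200 genes with the largest rise to Kupffer cells are given here for these only, not antibodies, TGF-beta or sterols. DLL4 raised 36 and lowered 1 of 102 measured in control BMDMs (camera adjusted p = 7.7e-14, 0.0019 with estimated correlation), 31 and 3 in Smad4 knockout BMDMs (camera adjusted p = 3.4e-12, 0.0031 with estimated correlation), and 32 and 1 of 120 in C57BL/6J BMDMs at 24 h (camera adjusted p = 7.2e-13, 0.0018 with estimated correlation). DAPT lowered 24 and raised 1 (camera adjusted p = 3.3e-16, 0.0011 with estimated correlation). In bone marrow monocytes DLL4 raised 46 and lowered 25 of 103 (camera adjusted p = 4e-04, 0.25 with estimated correlation). LY411575 in the animal lowered 43 and raised 15 of 157 (camera adjusted p = 0.00095, 0.16 with estimated correlation).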

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

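The tests of explanations below, and those of other groupings, were chosen after the results were seen. Single libraries far from the rest of their group were looked for in the 2 groups of 4 to 10 libraries, with 86 tests and 4 found, where chance alone marks about 1 in 20. Blood monocyte library 3 had erythroid genes at a mean log2(TPM + 1) of 7.11 against 5.44 to 5.72 in the others. The pooled blood monocyte library had Slc40a1 at 0.37 against 0.62 to 0.64, and library 6a10 had Ccr2 at 10.31 against 10.73 to 10.81. Cyp3a11 stood at 3.2 in antibody-treated library 1 against 5.25 to 5.6.

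Tests of a difference between groups passed for 123 genes in the answer to TGF-beta with and without Smad4, and for 532 genes between LY411575 and the antibodies. In libraries no comparison used, Smad4 knockout BMDMs given DLL4 and TGF-beta, Pmepa1 had a mean of 20 TPM against 1.05 with DLL4 alone, and Tmem119 22.1 against 6.01.

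Against monocytes, the real grouping of the 7 libraries called the most genes of 35 groupings for Kupffer cells (3996, highest other 2997). The same held at 24 h (3802, 2572), 168 h (3296, 2311) and 336 h (3498, 2481). As 1 of 35 is the lowest share possible, chance is not excluded. Against Kupffer cells at 24 h (1670, highest other 3), 168 h (454, 246) and 336 h (435, 11), 10 groupings are too few for a share under 0.05.

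Rpl34, Rpl30, Hmgn2 and Morf4l1 were low in some Smad4 libraries. In Kupffer cells 2 genes had a control library below 0.25 of the highest knockout library, which argues against loss of Smad4 for these, Rpl30 (31.9 and 2.07 TPM in controls, 61.9, 29.9 and 37.4 in TIM4-positive knockouts) and Morf4l1 (4.2 and 4.63, 2.81, 19.7 and 19.3). Hmgn2 reached a group mean of only 2.9 TPM, too low to decide. Rpl34 had 36.9 and 2.37 TPM in controls and at most 1.81 in knockouts. Its lower control lay 1.31-fold above the highest knockout, and with controls this far apart loss of Smad4 and the donors cannot be told apart for it. In BMDMs all 4 genes separated (Rpl34 87.6 to 119 TPM in controls, 0 to 0.83 in knockouts), so loss of Smad4 in BMDMs and the donors cannot be told apart. A change of read processing in whole tables or genotypes is argued against by a 15.6-fold difference between the 2 control libraries for Rpl34. A strain variant against the reference stays open for Rpl30 and Morf4l1. The pair of knockout libraries sharing a number lay within 1.13-fold for both, which any cause common to it would give. The labels do not say that the number is 1 animal. Hmgn2 differed in that pair, at 0.416 and 1.13 TPM.

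Smad4 knockout BMDMs kept part of the answer to TGF-beta. A median of 34.3 ± 1.1% of the TPM change in control cells was left for 205 of 268 genes that rose. It was 36.6 ± 1.4% for 110 of 160 that fell (SE over genes, not libraries). These had a mean of at least 10 TPM in either group, and 202 and 108 kept direction. The 10th to 90th percentiles were 21.3 to 54.7% and 16.1 to 66.7%. The control TGF-beta pair differed widely (chi-square 27.89 per degree of freedom). A share of cells without deletion may give the 2.3 points (SE 1.8 over genes) between the medians. A single share for every gene is not shown. Smad4 itself was left at 37 to 45.9% of control across treatments. The kept part of the log2 difference had an interquartile range of 0.172 for genes that rose, which leaves out those at the ends. A response of particular genes that does not need SMAD4 thus stays open, as does partly working SMAD4 in every cell, which was not tested.

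Hepatocyte transcripts moved apart between the LY411575 and antibody experiments. The list made up 0.119 and 0.118% of TPM in LY411575 controls and 0.194, 0.193 and 0.197% in treated libraries, against 0.975 and 0.457% in antibody controls and 0.147, 0.293, 0.181 and 0.443% in treated libraries, with Alb at a mean of 220.7, 465.9, 1773 and 567.5 TPM in the 4 groups in turn. Hepatocyte RNA carried over from the tissue could give this, but 1 of 17 measured genes, Trf, went the other way (log2 -0.40, not called), which leaves it undecided. RNA of all other liver cells carried over alike is argued against, since the sinusoidal endothelium list had a median log2 difference of -0.726 (genes from -1.665 to 0.278) and the stellate list -0.974 (5 genes, -1.531 to 0.04) against 2.588 for hepatocytes. Sex, which differs between the experiments, stays open and was not tested.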

How the results depend on the processing

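The settings limma-voom, fits within Kupffer cells or BMDMs alone, and the extra sets of shared calls were chosen after the data were seen. Of 71 main results, 65 stayed within their limits under a pseudocount of 0.25, 64 under quantile normalization, 51 with no expression filter (8 moved) and 52 in limma-voom (7 moved). Of the results for single genes and lists, 4641, 4346, 4453 and 4445 kept direction and side of the threshold in turn. Fits within Kupffer cells alone kept 2 main and 143 further results with 6 weaker, and BMDMs alone 1 main and 34 further results with 2 stronger. The cause of the differences below was not tested, apart from the fewer libraries where 1 is left out and the higher floor for adjustment with no filter. Shallow libraries limit genes of few reads most.

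Under quantile normalization the median of all genes moved by over 0.1 in 5 comparisons. The shifts were -0.105 at 48 h against monocytes, -0.106 in the TIM4-negative libraries labelled Nr1h3 knockout, -0.114 in the STAB2-low fraction, -0.122 for TGF-beta on DLL4 at 72 h and 0.133 for TGF-beta on DLL4 in monocytes. The share of called genes that were higher also moved by 5 points or more against Kupffer cells at 12 h (42.4 to 50.1%), 72 h (60.6 to 53%) and 168 h (31.9 to 39.7%), in the STAB2-low fraction (59.4 to 51.4%), TIM4-positive Smad4 knockouts (61.5 to 52.8%), DLL4 at 72 h (75.7 to 66.8%), TGF-beta on DLL4 at 72 h (71.3 to 61.7%) and desmosterol (52 to 58.6%). Signs turned for Tyms against monocytes in Kupffer cells (-0.026) and at 24 h (-0.098), Paqr9 at 24 h (-0.147), Zbtb46 at 48 h (-0.115) and 72 h (-0.013), Klrb1c at 336 h (-0.051) and the list of genes highest at 24 h in the TIM4-negative libraries labelled Nr1h3 knockout (-0.028). Nr1h3 knockout BMDMs had 22 genes and the STAB2-intermediate fraction 0. Positions for genes higher in Kupffer cells were 61 at 48 h, 75.3 at 72 h and 83.4 at 336 h, and for genes lower in them 90.8 at 72 h and 85.1 at 336 h.

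With a pseudocount of 0.25 the STAB2-intermediate fraction had 2 genes and sterols on DLL4 and TGF-beta shared 1 lowered gene. Positions for higher genes were 76.9, 87.5 and 83.6 at 48, 72 and 336 h, and for lower genes 91.4 at 336 h. With no filter the STAB2-intermediate fraction had 0 genes, Smad4 knockout Kupffer cells 60 (TIM4-positive) and 83 (TIM4-negative), the genotype test on DLL4 3, and the Smad4 and Nr1h3 pairs shared 15 and 9 genes (TIM4-positive, higher and lower) and 15 and 26 (TIM4-negative). In limma-voom Nr1h3 knockout BMDMs had 87 genes, the STAB2-intermediate fraction 11, TGF-beta in Smad4 knockout BMDMs 90, the genotype test on DLL4 1, the antibodies 367, desmosterol in the mix 41, and TGF-beta on DLL4 shared 108 lowered genes. With an estimated correlation 72 of 387 called list results and 23 of 50 called results of the lists from the first table kept their calls.

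Replicate numbers were not stated to be pairs. Taking them as a block left 37 main results within their limits and gave 27 genes in the STAB2-intermediate fraction. Median correlations within the block were 0.015, 0.136, 0.009, 0.007, -0.031 and 0.018 in 6 tables. No paired analysis was possible because the groups share no numbers in the time course and, apart from 1 pair, in the Smad4 Kupffer cells.

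With single libraries left out, counts ran from 11 to 21 for Nr1h3 knockout BMDMs, 1 to 20 for the STAB2-intermediate fraction, 1 to 80 and 1 to 104 for TIM4-positive and TIM4-negative Smad4 knockout Kupffer cells, 97 to 225 for the genotype test on TGF-beta, 0 to 2 for that on DLL4, 132 to 344 for the antibodies, 323 to 629 for the difference between LY411575 and the antibodies, 16 to 29 for desmosterol and 16 to 37 for it in the mix. Positions for genes higher in Kupffer cells ran from 71.1 to 73.0 at 48 h, 79.8 to 86.1 at 72 h and 76.9 to 82.7 at 336 h, and for lower genes from 90 to 94.2 at 336 h. Shared calls of the Smad4 and Nr1h3 pairs ran from 0 to 29 (higher) and 0 to 15 (lower) in TIM4-positive cells, and from 0 to 37 and 1 to 50 in TIM4-negative cells. The sterols shared 1 to 2 lowered genes alone and on DLL4 and TGF-beta. The interferon list in the TIM4-positive libraries labelled Nr1h3 knockout had a median from -0.41 to 0.326, turning without control library 1.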

Other observations

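Other groups of genes moved in ways the comparisons did not lead with. In bone marrow monocytes given DLL4, monocyte list genes split 3 higher and 7 lower, while the interferon-induced Gbp2b stood at 262 ± 1.16 against 0.044 ± 0.0622 TPM. In 72 h BMDM cultures given DLL4, the lysozyme gene Lyz2 fell from 21780 ± 518 to 6140 ± 97.7 TPM (log2 -1.83 ± 0.06), with Ccl6 and Siglec1 at -2.12 and -1.82. The serine synthesis gene Psat1 was higher in liver macrophages at 72 h than in Kupffer cells, at 58.6 ± 20.3 against 2.23 ± 1.2 TPM, next to the full set of cell cycle genes, and Asns, which makes asparagine, rose with LY411575 from 1.42 ± 0.119 to 22.1 ± 2.51 TPM.

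The pancreatic protease gene Ctrb1 stood at 15 and 143 TPM in the 2 libraries of liver macrophages at 48 h against 1.01 ± 1.15 in the 3 of Kupffer cells. Cd207, the langerin gene, was at 1305 ± 146 TPM at 336 h against 524 ± 476 in Kupffer cells.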
